A study of Mus musculus with 4 samples.

How the data were processed

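Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 10T1/2 cells, a mouse embryonic fibroblast line. Per the labels there were 4 libraries, 2 from wild-type cells and 2 from cells in which Ranbp2 had been knocked out with CRISPR-Cas9. Library names in the labels number the wild-type libraries 1 and 3 and the knockout libraries 2 and 3, and any others were not analysed here. Per the series' design text the knockout cells were 1 clone grown from a single sorted cell. The labels do not say that replicates came from separate cultures, so any p-value over libraries measures only the spread between these samples, which may be technical.

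Per the submitters' processing notes, the genome build was mm10 and the tools named were cutadapt, Bowtie2, deepTools, MACS2, DiffBind 2.2.12 and DESeq2, with no role or order given. The authors deposited 1 list of peaks per library, and the peak names show that peaks were called in each library separately. In the deposited peak lists, the score of a peak is 10 times its −log10 q with the decimals dropped, apart from 0.0376% of peaks. The deposited fold enrichment is the ratio at the peak summit over the local background of the same library. The authors' −log10 p and −log10 q are the caller's values for that summit, and the lowest −log10 q in each of the 4 deposited lists lies just above 3. These values are the authors', and they were used here only to describe, rank or filter peaks within a list. The authors also deposited 2 lists of differential regions, 1 enriched in knockout cells and 1 enriched in wild-type cells, as positions without a fold change, p-value or rank. The threshold and settings behind these 2 lists are not given in the sources used here.

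The files hold no read counts, so the sequencing depth of each library is unknown and no test on counts was made. The length of a peak list moves with depth, and a region missing from a list may be a region below that list's threshold. Intervals on shares of peaks are Wilson 95% intervals and cover counting error only.

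Peaks of the 4 lists were joined into merged regions wherever they overlapped by at least 1 bp, and a region was scored as present in a library that had a peak in it. Pairs of libraries were compared by the Jaccard index, the length of shared peak sequence over the length of the combined peak sequence. Tests over the 4 libraries were two-sided exact permutation tests, for which 2 libraries against 2 cannot give a p below 0.333. The deposited differential regions were compared with a background of 23116 merged regions present in at least 2 lists, leaving out those that overlap the list tested. Gene-end shares, chromosomes and gene lists were tested with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 44 tests for chromosomes and over 38 for gene lists. Chromosomes and scaffolds with at least 20 background regions were tested, besides the autosomes and X. In these tests regions or genes are the units, not libraries, so their p-values carry no replicate error between cultures.

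Gene positions were taken from a table of RefSeq gene spans for the GRCm38.p6 assembly, the same primary coordinates as mm10, with 21887 protein-coding genes on assembled chromosomes. This table gives no strand, so the planned distance to a transcription start was replaced by a position within 1 kb of either end of a protein-coding gene, called a gene end below. Both starts and 3′ ends of genes therefore count, and any start further inside a gene span is missed. Counts at gene ends are therefore not counts of promoters. The gene named for a region is the protein-coding gene that contains it, or else the nearest one within 100 kb. A genome sequence was not used here, so the planned motif test and the match of the guide sequence were not run.

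Before the data were examined, the tests, the background, most alternatives, 19 gene lists and the naming rule were fixed. The rule named Ranbp2, the genes nearest the 15 highest-ranked regions of each differential list, every gene of a fixed list nearest a differential region or with a gene-end peak in both libraries of 1 genotype only, and the genes nearest the 10 best-ranked regions present in both libraries of 1 genotype only. The differential lists carry no rank, so their regions were ranked by the highest −log10 q of an overlapping peak in the enriched genotype, which is peak strength and not the size of the difference. The fixed lists covered the RANBP2 complex with nuclear pore and SUMO genes, fibroblast, smooth muscle, skeletal muscle, adipogenic, osteogenic and chondrogenic genes, and inflammatory, interferon, cell cycle, AP-1, TGF-beta with BMP and Wnt, Hox and chromatin genes. They also held markers of epithelial, endothelial, immune, neural and pluripotent cells and a set of ubiquitous promoters. Of the listed symbols, Mx1 and Mx2 were not matched to a protein-coding gene of the table and were left out, which left 302 genes.

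Alternatives were a −log10 q minimum of 3 or 5, the same number of top-ranked peaks in each list (13877, the length of the shortest), autosomes only, and an overlap of 50% of the shorter interval. Others were windows of 250 bp on each side of summits, gene-end windows of 0.5 kb and 3 kb, other backgrounds, a nearest-gene limit of 20 kb, and each library left out in turn. The minimum of 5, the tests stratified by chromosome or by peak strength in 5 bins (by chromosome class also in 10 and 20), assembled chromosomes only, the replicate numbers as a block (planned for knockout-only regions), the backgrounds from 3 libraries, and all alternatives for the gene-end peaks of fixed lists and for Ranbp2 were chosen after seeing the data.

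The chromosome test was tested on simulated data by drawing 190 of 22903 background regions 100 times. With no planted change, chromosome 17 was called in 0 draws and any chromosome in 5. With regions of chromosome 17 drawn at 2, 3 and 5 times their weight, it was called in 27, 82 and 100 draws. Overlap counts were checked against bedtools in 12 ordered pairs of libraries, and 0 pairs differed. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.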

Results

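Accessible chromatin was mapped in 10T1/2 mouse embryonic fibroblasts with intact Ranbp2 and in a clone in which Ranbp2 was knocked out, with 2 ATAC-seq libraries per genotype. Ranbp2 encodes a large nucleoporin on the cytoplasmic face of the nuclear pore that binds Ran and acts as a SUMO E3 ligase. The comparison asks which regions of open chromatin differ between cells with and without this protein. The wild-type libraries had 33721 and 18511 peaks, covering 7.12 and 3.77 Mb, and the knockout libraries had 13877 and 24292 peaks, covering 2.68 and 4.83 Mb. Median peak widths ran from 164 to 181 bp.

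The Ranbp2 promoter was open in all 4 libraries. Ranbp2 (gene 19386) lies on chromosome 10 at 58446852-58494155 in mm10, and a peak with its summit at 58446771 or 58446794, less than 1 kb from the gene's start coordinate, was present in each library. Its fold enrichment, as the authors' caller gave it, was 18.1 and 13.0 in the wild-type libraries and 8.22 and 14.4 in the knockout libraries. These folds belong to separately called lists and were not tested against each other. A small coding or splice-site lesion need not close a promoter, so this peak does not check the knockout. The nearest differential region of the wild-type-enriched list lay 123.5 kb away, near Lims1, an adaptor of focal adhesions.

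Wild-type and knockout cells shared a large set of accessible regions, and each genotype had some that only its own 2 lists contained. The 4 lists merged into 39136 regions, of which 10977 (28.1%) had a peak in all 4 libraries and 16020 (40.9%) in a single one, mostly wild-type replicate 1 (11055) or knockout replicate 2 (4053). Regions present in both wild-type and neither knockout library numbered 2552, and regions present in both knockout and neither wild-type library numbered 373. The 4 pairs made of 1 library of each genotype had between 13 and 3178 such regions, and the highest count, of wild-type replicate 1 with knockout replicate 2, the longest lists, exceeded those of both genotypes. When every list was reduced to its 13877 top-ranked peaks, these counts became 1233 and 1040, and those of the mixed pairs lay between 215 and 341. The counts also depended on single libraries. With 1 library left out at a time, wild-type-only regions ran from 2721 to 13614 and knockout-only regions from 423 to 4430.

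The best-ranked knockout-only regions lay inside Smo, the signal transducer of the Hedgehog pathway (chromosome 6, 29748843-29748948), and inside Rras2, a Ras-family GTPase (chromosome 7, 114060759-114060859). Their peaks ranked on average at percentiles 92.1 and 78.1 of the knockout lists. Others lay inside Pkhd1, Col8a1, a network-forming collagen, and Cipc, a circadian clock regulator, near Ccdc66, Akr1b3, Llgl1 and Ap1s1, and on the unplaced scaffold JH584304.1. The best-ranked wild-type-only regions lay inside Efna5, an ephrin ligand (chromosome 17, 62737542-62737639, 98 bp wide, percentile 99.6), and inside Gstt2, a glutathione transferase (chromosome 10, 75837209-75837666, percentile 89.9). Others lay inside Arhgap26, Exo5, Cd82, a tetraspanin, Adamts6, a secreted metalloprotease, and Fam135b, and near Sgk1, Reep3 and Cdh5. Of the knockout-only regions 14 (3.75%, Wilson 95% interval 2.25 to 6.20) lay at gene ends, against 483 (18.9%, 17.5 to 20.5) of the wild-type-only regions. These regions were weaker than most, with median rank percentiles of 27.7 and 34.4, and 9 and 19 of them overlapped the deposited differential lists. None of the knockout-only regions named here was among those 9. Of the wild-type-only regions named here, those of Gstt2, Reep3 and Cd82 were among the 19, and the others, that of Efna5 included, were not.

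The number of peaks did not separate the genotypes. It averaged 26116 ± 10755 in wild-type and 19084.5 ± 7365 in knockout libraries (SD, n = 2 each; exact permutation p = 0.667, where the smallest possible is 0.333), and without wild-type replicate 1 the knockout mean was higher by 573.5 peaks. The mean Jaccard index was 0.494 within genotypes and 0.475 between them. One of the other 2 ways of pairing the 4 libraries, which joined the longer lists and the shorter lists, gave a wider gap (0.505 against 0.470). With 13877 peaks per list, the gap between genotypes grew to 0.0630 and both other pairings gave negative gaps, -0.0499 and -0.0131. With the lists as deposited, the gap between genotypes reversed without wild-type replicate 1 (-0.0391) or without knockout replicate 1 (-0.0264). With 3 possible pairings, no share under 0.05 can be reached. Peaks at gene ends made up 29.0% and 39.0% of the wild-type and 39.8% and 32.3% of the knockout lists (exact permutation p = 0.667, n = 2 each), so the spread within each genotype was larger than the difference of 2.05 points. That difference became -3.35 points with equal list lengths.

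**Figure D1:**
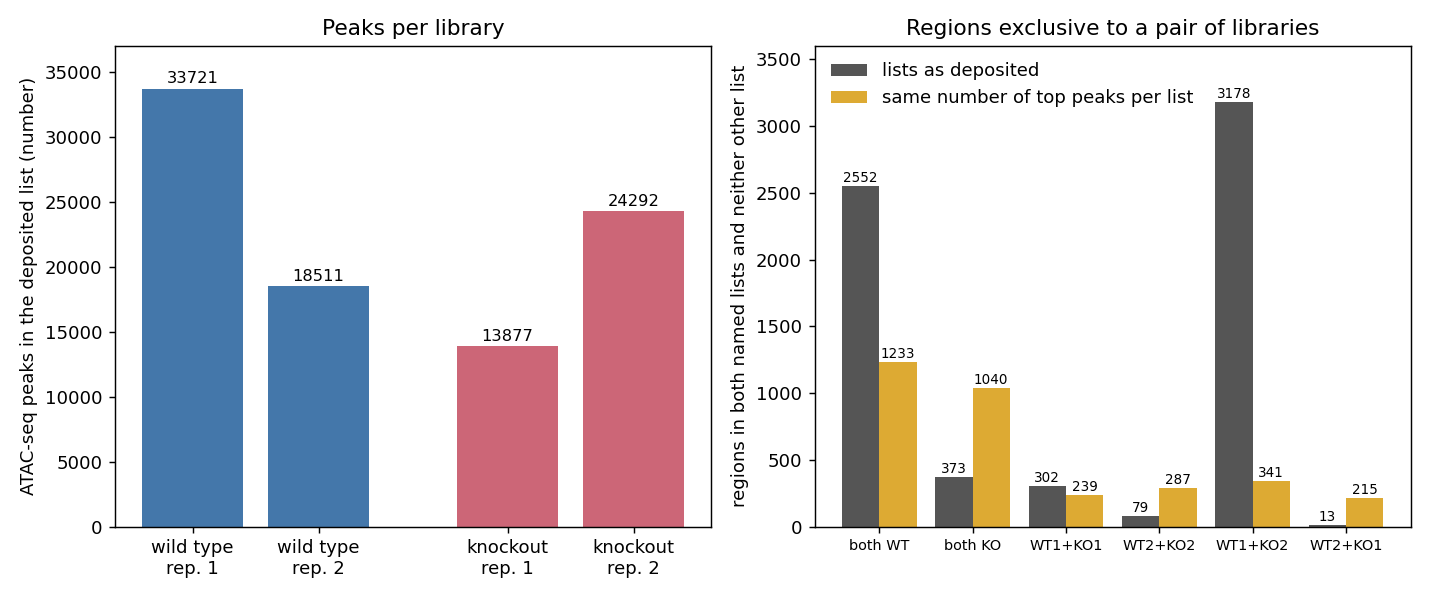
Number of peaks in the deposited list of each library (left), and number of merged regions present in both named libraries and in neither other library (right; WT, wild type; KO, knockout; numbers after them are replicates), with the lists as deposited (grey) and with the 13877 top-ranked peaks of each list (yellow). With equal list lengths, the pairs of 1 genotype have 1233 and 1040 regions of their own and the mixed pairs 215 to 341.

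The authors' deposited lists name 189 regions as enriched in knockout cells and 190 as enriched in wild-type cells, nearly all of them about 400 bp wide. Whether these lists rest on the 4 libraries alone is not given in the sources used here. Of the 15 wild-type-enriched regions with the strongest peaks, 14 lay at gene ends. They lay at those of Rab5b, an early endosome GTPase (chromosome 10, 128696251-128696650, highest −log10 q 273.6), Csnk1g2, a casein kinase, Mbd3, a subunit of the NuRD chromatin remodelling complex, Izumo4, Dazap1, an RNA-binding protein, Pa2g4 and Hmg20b, a partner of the CoREST complex, all on chromosome 10. They also lay at gene ends of Sp1, a zinc-finger transcription factor, Srebf2, the main transcription factor of cholesterol synthesis, Tnrc6b, a factor of microRNA silencing, and AW549877, all on chromosome 15. Srd5a1 on chromosome 13, Tmem115 on chromosome 9 and Ubald2 on chromosome 11 completed this group, and the region inside Tarbp2, a Dicer partner, lay 1.97 kb from the nearest gene end. Each of these 15 regions had a peak in all 4 libraries.

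The knockout-enriched regions with the strongest peaks mostly lay away from gene ends. Of the 5 strongest, 2 were on the unplaced scaffold GL456392.1 (−log10 q 730.5 and 279.8) and 1 was on JH584304.1. Among the rest were regions inside Cobl, an actin nucleator (chromosome 11, 12374928-12375327, 89.9 kb from the gene's nearest end, −log10 q 404), Cdsn, Myo1c, an unconventional myosin, and Pex2, a peroxisome assembly factor. Regions outside genes lay 42.6 kb from Tex44, 97.5 kb from Tcp10c, 19.6 kb from Cystm1, 57.7 kb from Asb7 and 76.7 kb from Chd7, a chromatin remodeller. Gene ends of Gigyf2, 1600012H06Rik and Ilrun were the exceptions among these 15. Each of the 15 regions had a peak in all 4 libraries.

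Most differential regions were open in both genotypes. Of the 189 knockout-enriched regions, 100% and 91.5% had a peak in knockout replicates 2 and 1, and 94.2% and 65.1% in wild-type replicates 1 and 2. Of the 190 wild-type-enriched regions, all had a peak in both wild-type libraries, 77.9% in knockout replicate 1 and 88.9% in knockout replicate 2. A peak in both libraries of the named genotype and neither of the other was found for 9 knockout-enriched regions (4.76%, Wilson 95% interval 2.52 to 8.80) and 19 wild-type-enriched regions (10.0%, 6.5 to 15.1). Named after their values were seen, the 9 lay in or near Ski, Niban1, Slc38a1, Wdr33, Kank1, Phlpp1, Atxn1, Shq1 and Tcte2, and the wild-type regions with the highest −log10 q lay at Gstt2 (98.2), Reep3 (84.9), Cd82 (63.8) and Prex1 (55.9). The knockout share depended on list length, being 33.9% with 13877 peaks per list. It was 29.6% without wild-type replicate 1, which removes a library and not only list length. The wild-type share was 22.1% without knockout replicate 2.

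Fewer knockout-enriched and more wild-type-enriched regions than background regions in at least 2 lists lay at gene ends. Of the knockout-enriched regions 18 of 189 (9.52%) lay at gene ends, against 35.1% of background regions (odds ratio 0.195, 95% interval 0.120 to 0.316, Fisher's exact p = 7.68e-16). Of the wild-type-enriched regions 87 of 190 (45.8%) lay at gene ends, against 34.8% of background regions (odds ratio 1.58, 1.19 to 2.11, Fisher's exact p = 0.00215). The gene table has no genes on unplaced scaffolds, and without the 15 knockout-enriched regions there the odds ratio was 0.210 (18 of 174, Fisher's exact p = 5.12e-14). Inside gene spans lay 103 (54.5%) of the knockout-enriched and 121 (63.7%) of the wild-type-enriched regions, which was not tested. The median distance to a gene end was 11.6 kb in the knockout and 1.94 kb in the wild-type list. By the same exact test, the wild-type excess was not kept against background regions present in all 4 lists (odds ratio 0.955, p = 0.770) or without wild-type replicate 1 in the background (1.27, p = 0.118), and it was larger against regions present in at least 1 list (2.43, p = 3.33e-09). On chromosomes 9, 10, 13, 15 and 19 the wild-type odds ratio was 2.79 (1.95 to 3.98) and on the other assembled chromosomes 0.435 (0.231 to 0.817). Within bins of peak strength the Mantel-Haenszel odds ratio was 0.862 (0.639 to 1.16). The knockout odds ratio was 0.343 (0.174 to 0.675) on chromosomes 1, 17 and 18 and 0.145 (0.0704 to 0.298) on the other assembled chromosomes, and under the alternatives run on the whole list lay between 0.117 (background in all 4 lists) and 0.30 (background in at least 1 list).

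Differential regions were concentrated on a few chromosomes, different ones in the 2 lists. The wild-type-enriched list had 41 regions on chromosome 10, where the background predicts 9.51 (odds ratio 5.22, adjusted p = 1.46e-13, Fisher's exact tests with Benjamini-Hochberg adjustment here and below). It also had more than expected on chromosomes 9 (23 against 9.71, adjusted p = 0.00126), 13 (22 against 7.68, 0.000106), 15 (22 against 9.40, 0.00174) and 19 (20 against 6.23, 6.83e-05). These 5 chromosomes held 128 of its 190 regions (67.4%) and 22.8% of the background. The knockout-enriched list had 32 regions on chromosome 17 against 8.70 expected (odds ratio 4.22, adjusted p = 4.16e-09), 22 on chromosome 1 against 11.8 (adjusted p = 0.0213) and 12 on chromosome 18 against 5.74 (adjusted p = 0.0415). These 3 held 66 of its 189 regions (34.9%) and 14% of the background. A further 12 of its regions lay on the scaffold JH584304.1, against 0.569 expected (adjusted p = 5.98e-11).

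Some of the chromosomes that led 1 list held few regions of the other. The wild-type list had 1 region on chromosome 17 against 9.0 expected (adjusted p = 0.00758) and 4 on chromosome 1 against 12 (adjusted p = 0.0415). The knockout list had 3 on chromosome 10 (9.78 expected), 3 on chromosome 9 (9.82) and 1 on chromosome 13 (7.82), with adjusted p from 0.0212 to 0.0415, while its counts on chromosomes 15 and 19 and that of the wild-type list on chromosome 18 did not pass. Fewer regions than expected were also found on chromosome 8 in both lists and on chromosomes 3, 7, 12, 14 and 16 in the wild-type list. The counts of a list share 1 total, so its excess on some chromosomes lowers its counts on the others. These low counts and their adjusted p are therefore not independent of the excess. Whether any of them go beyond it was not tested. In all, 8 tests passed the threshold in the knockout and 13 in the wild-type list, and with the other backgrounds 6 to 8 and 12 to 13 did.

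**Figure D2:**
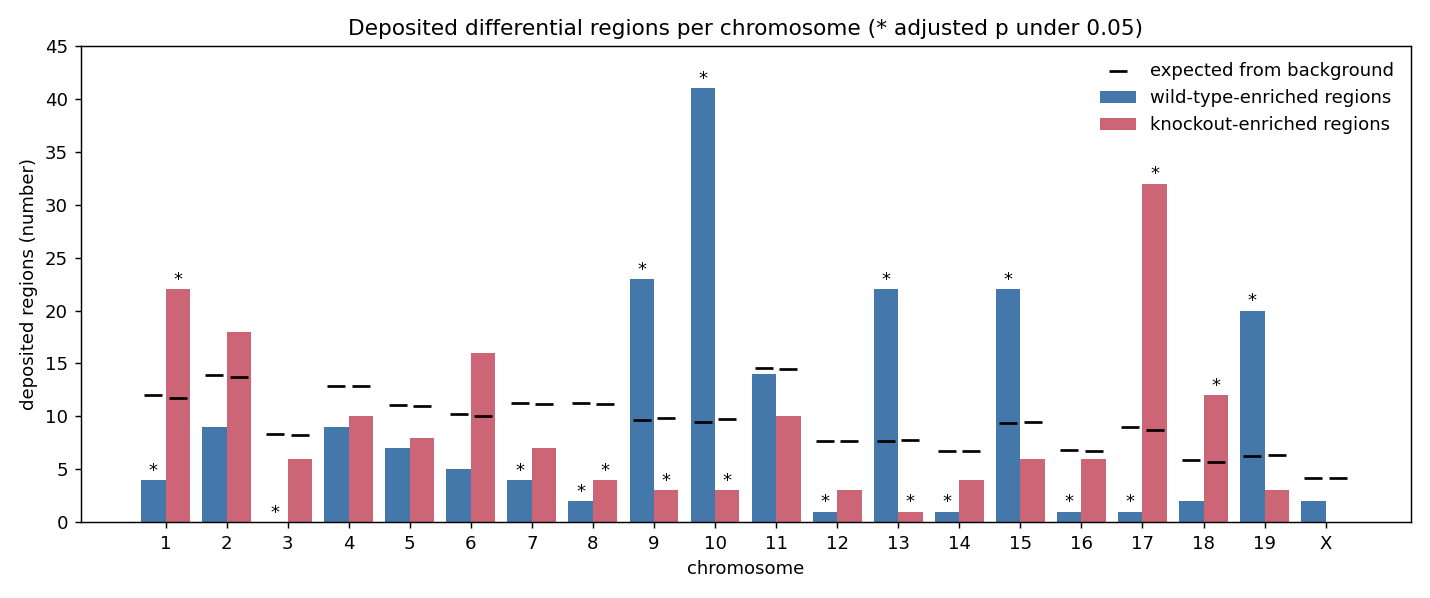
Number of deposited differential regions on each assembled chromosome (bars; blue, wild-type-enriched; red, knockout-enriched), with the number expected from the background regions (black lines); stars mark an adjusted p under 0.05. The highest bars are the 41 wild-type-enriched regions of chromosome 10 and the 32 knockout-enriched regions of chromosome 17.

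**Figure D3:**
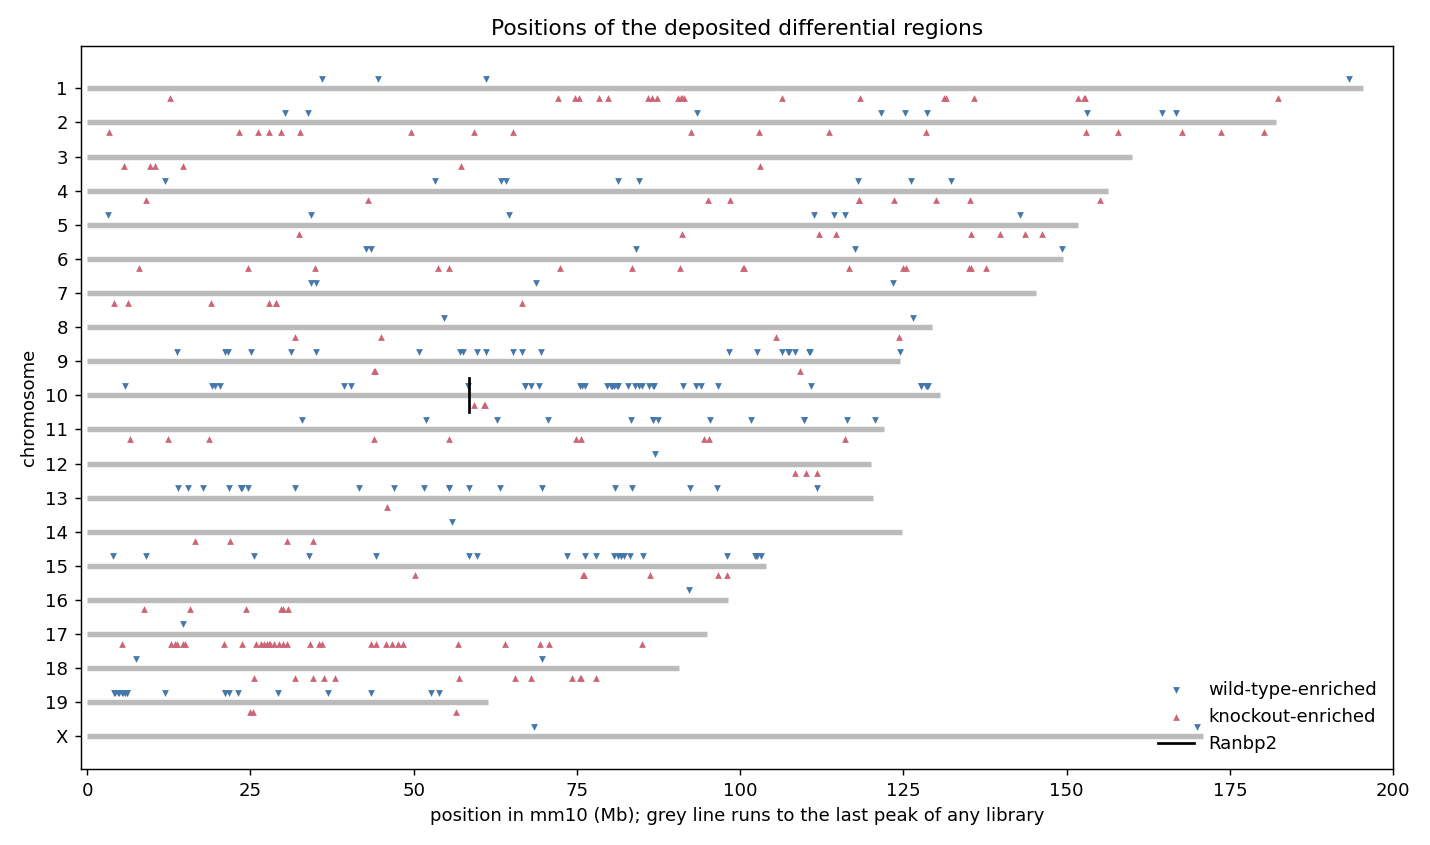
Positions of the differential regions along the assembled chromosomes in mm10, in Mb (blue triangles above each line, wild-type-enriched; red triangles below, knockout-enriched), with Ranbp2 on chromosome 10 as a black bar; 15 knockout-enriched regions on unplaced scaffolds are not drawn. Regions of 1 list occur along the length of chromosomes 9, 10, 13 and 15 (wild-type-enriched) and along much of chromosome 17 (knockout-enriched).

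Peaks outside the differential regions were also distributed differently over the chromosomes. After peaks overlapping either list were left out, chromosome 17 held 4.38% and 4.55% of wild-type but 5.35% and 5.33% of knockout peaks, and chromosome 13 held 4.71% and 4.21% of wild-type but 3.55% and 3.77% of knockout peaks. On each of the 8 chromosomes that led a list, both knockout libraries lay on the same side of both wild-type libraries as the list did. Over all 20 chromosomes the shares of the genotypes did not overlap on 13 (65.0%), where chance gives 33.3% for a single chromosome. The shares of a library sum to a fixed total, and all come from the same 4 libraries. The 20 chromosomes are therefore not independent, and the 65.0% was not tested. The ranks of 10608 regions present in all 4 libraries and outside both lists moved the same way on the 8 chromosomes that led a list. These regions did not follow the shares on every chromosome. On chromosome 4 the knockout shares were higher, but the regions ranked slightly lower in knockout in all 4 pairs (-0.0618 to -0.478 points). On chromosome 17 they ranked 4.36 to 5.05 percentile points higher in knockout than in wild-type libraries over the 4 pairs, on chromosome 13 the same difference ran from -7.69 to -4.36 points, and the largest shift between replicates of 1 genotype on any chromosome was 2.85 points. Chromosomes 1, 8 and 17 were higher and chromosomes 9, 10, 13, 15 and 19 lower in knockout by more than that in each of the 4 pairs.

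**Figure D4:**
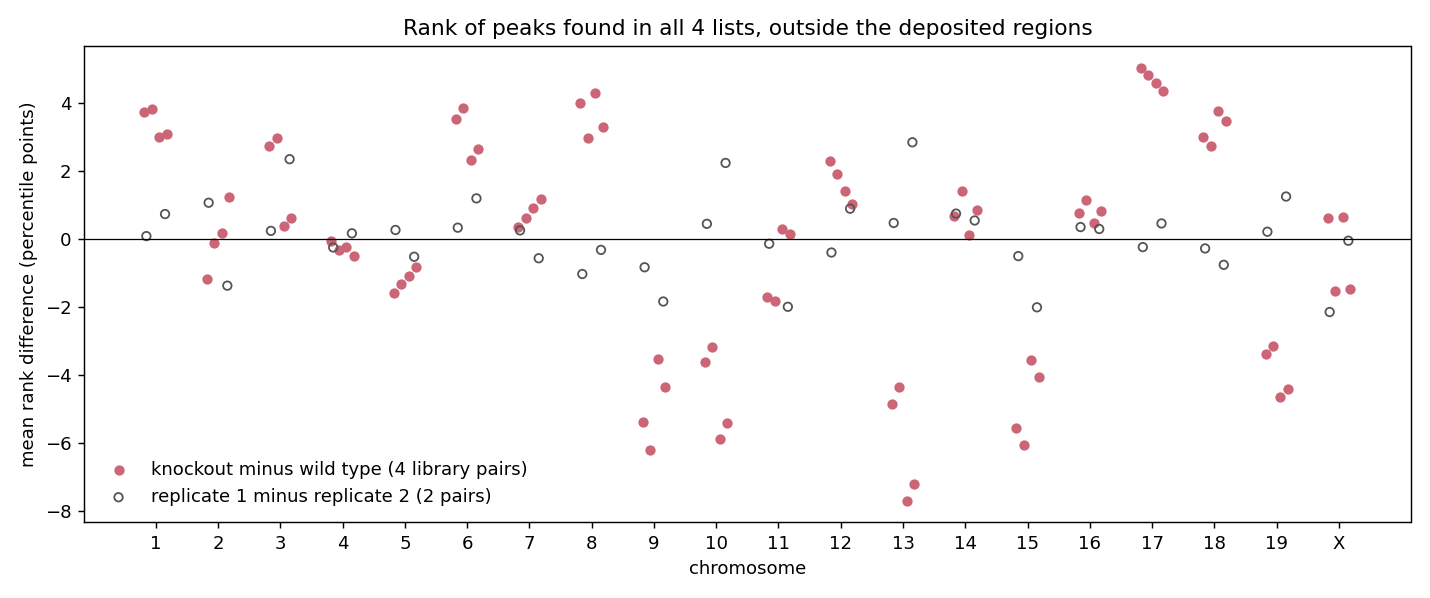
Mean difference in rank, in percentile points, of regions with a peak in all 4 libraries and outside the differential lists, by chromosome (filled, each knockout minus each wild-type library; open, replicate 1 minus replicate 2 of each genotype). Chromosomes 9, 10, 13, 15 and 19 lie below 0 and chromosomes 1, 8 and 17 above 0 by more than 2.85 points in all 4 pairs.

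Each differential list had 4 genes of the fixed lists as nearest genes. Knockout-enriched regions had as nearest gene Jun, an AP-1 subunit (30.2 kb away), Cebpb, an early adipogenic transcription factor (23.0 kb), Thy1, a fibroblast surface marker (60.6 kb), and Col2a1, the cartilage collagen, which contained its region. Wild-type-enriched regions lay inside Fbn1, the microfibril protein fibrillin, Cebpa, a later adipogenic transcription factor, and Actb, the cytoskeletal actin, and 42.1 kb from Mef2c, a muscle transcription factor. Of 19 lists, 0 passed for either set of regions by Fisher's exact test after adjustment, and 0 had an unadjusted p under 0.05. For a single call, neural and pluripotent markers needed both of their 2 background genes near regions and the other lists 3 or 4, except immune markers, whose 1 background gene could not give a call. A lack of list genes near regions could not be called in any list.

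Fixed-list genes with an accessible gene end mostly had it in both genotypes. Of 302 genes, 147 and 124 had a gene-end peak in the wild-type libraries, 104 and 126 in the knockout libraries, and 101 in all 4. In both wild-type and neither knockout library were Pdgfrb and Twist1, a receptor and a transcription factor of mesenchymal cells, Myl9, a smooth muscle myosin light chain, Cebpa, Runx2, the osteoblast transcription factor, Hdac4 and Sdha. There were 0 such genes for the knockout libraries, and the 4 mixed pairs of libraries had 0 to 3. Over all merged regions, 483 wild-type-only and 14 knockout-only regions lay at gene ends, so this imbalance was not particular to the fixed lists. With 13877 peaks per list the gene counts were 9 for wild type and 1 for knockout, and 3 of the 7 wild-type genes were among the 9. These were Cebpa, Runx2 and Sdha, while Pdgfrb, Twist1, Myl9 and Hdac4 were not among the 9. Without wild-type replicate 2 or knockout replicate 2, which leaves the longest or the shortest list alone for its genotype, 24 and 23 genes were wild-type-only.

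The group closest to RANBP2 itself, the RANBP2 complex with nuclear pore and SUMO genes, had gene-end peaks at 22 and 21 of 24 genes in wild-type and 19 and 21 in knockout libraries. Fibroblast genes had them at 14 and 10 of 20 in wild-type and 5 and 9 in knockout libraries, AP-1 and immediate early genes at 12 and 12 of 14 against 11 and 12, and ubiquitous promoters at 17 and 16 of 20 against 14 and 16. For cell cycle and p53 genes the counts were 15 and 11 against 10 and 12 of 18, for inflammatory genes 9 and 7 against 5 and 7 of 20, and for interferon response genes 6 and 5 against 2 and 5 of 15. TGF-beta, BMP and Wnt genes had 13 and 13 against 13 and 14 of 21, chromatin and lamina genes 17 and 14 against 15 and 15 of 21, and Hox and patterning genes 6 and 5 against 5 and 5 of 26. Smooth muscle genes had 4 and 4 against 3 and 3 of 12, skeletal myogenic genes 2 and 2 against 1 and 2 of 14, adipogenic genes 3 and 2 against 1 and 2 of 12, and osteogenic and chondrogenic genes 3 and 2 against 0 and 1 of 14. Markers of epithelial, endothelial and pluripotent cells had 0 gene-end peaks in all 4 libraries, immune markers 1 and 0 against 0 and 1 of 12, and neural markers 3 and 0 against 0 and 1 of 11. Knockout replicate 1, the shortest list, had the lowest or an equal lowest count in each of these lists except chromatin and lamina genes.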

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

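Of 134 alternative values, 110 kept their direction and their side of the threshold or moved by less than the spread between replicates, 15 moved, 8 reversed and 1 lost significance. The −log10 q minimum of 3 removed 0 peaks and so tests nothing. Its values are counted among the 110, as are those of the replicate block, which are the same by construction. The 110 therefore overstate how much was tested. The minimum of 5, the stratified tests, the backgrounds from 3 libraries, assembled chromosomes only, the replicate block except for knockout-only regions and the alternatives for fixed-list gene ends and Ranbp2 were chosen after seeing the data. With the 13877 top-ranked peaks of each list, knockout-only regions rose to 1040 and wild-type-only regions fell to 1233, the share of knockout-enriched regions exclusive to knockout libraries rose to 33.9%, the difference in gene-end share of peaks turned to -3.35 points, and 1 fixed-list gene, Ctcf, was knockout-only. Here list length is the setting itself. The wild-type-enriched odds ratio for gene ends turned to 0.955 against regions in all 4 lists and to 0.862 within strength bins, where it is compared with regions of like strength; for the former the cause was not tested. Leaving out libraries 1 at a time gave peak number differences from -14636.5 (without wild-type replicate 2) to 573.5 (without wild-type replicate 1), Jaccard gaps from -0.0391 (without wild-type replicate 1) to 0.0762, and gene-end share differences from -2.95 (without wild-type replicate 1) to 7.06 points. The Jaccard gap (-0.0264) and gene-end difference (-1.72) also reversed without knockout replicate 1. Knockout-only regions ranged from 423 to 4430 (without knockout replicate 1; 1716 without wild-type replicate 1), and wild-type-only regions from 2721 to 13614 (without wild-type replicate 2; 6646 without knockout replicate 2). Exclusive shares ranged from 4.76% to 29.6% (without wild-type replicate 1) and from 10.0% to 22.1% (without knockout replicate 2). The wild-type gene-end odds ratio ranged from 1.27 (without wild-type replicate 1, Fisher's exact p = 0.118) to 1.53, and the cause was not tested. Fixed-list genes ranged from 0 to 3 (without wild-type or knockout replicate 1) for knockout and from 7 to 24 (without wild-type replicate 2) for wild type. Both genotypes use replicate numbers 1 and 2, but nothing states that they pair the libraries, and the rank deviations of same-numbered libraries correlated at 0.0299 over 10608 regions in all 4 lists. With the numbers as a replicate block, the mean differences are by construction the unpaired -7031.5 peaks and 2.05 points, and the pairs differed in sign (-19844 and 5781 peaks, 10.8 and -6.73 points; exact sign-flip p = 1, where 0.5 is the smallest possible). Regions gained in both pairs are by construction the same 373 and 2552. The motif test and its alternatives were not run. Depth is unknown, so a region missing from a short list cannot be read as closed.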

Other observations

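The tests of rank shifts outside the differential lists and of a tilt between gene ends and other regions were set before their results were seen, and the tests of chromosome-wide peak shares, list length, the arm of chromosome 10, peak strength, chromosome strata and regions on and off the leading chromosomes were chosen after.

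Within the wild-type-enriched list, regions on and off its leading chromosomes differed in kind and in peak strength, with median rank percentiles of 83.7 and 67.0. On chromosomes 9, 10, 13, 15 and 19, 75 of 128 regions (58.6%) lay at gene ends, among them those of Rab5b, Sp1 and Srebf2, against 12 of 62 (19.4%) elsewhere, such as those of Cebpa, Prex1 and Thbs2 (Fisher's exact p = 2.4e-07). Of the 62, 12 (19.4%) had a peak in both wild-type and neither knockout library, against 7 of 128 (5.47%). Away from its leading chromosomes the wild-type list was poorer in gene ends than the background of the same chromosomes (odds ratio 0.435, 0.231 to 0.817, Fisher's exact p = 0.00744), as was the knockout list (0.145, 0.0704 to 0.298, p = 1.89e-11). In the knockout list, 10 of 66 regions on leading chromosomes (15.2%) and 8 of 108 on the other assembled chromosomes (7.41%) lay at gene ends (Fisher's exact p = 0.126). The scaffold JH584304.1 held 12 knockout-enriched regions. Its peaks made up 0.231% and 0.324% of the wild-type and 0.504% and 0.366% of the knockout lists. They numbered 78 and 60 in wild-type and 70 and 89 in knockout replicates 1 and 2. The Wilson interval of wild-type replicate 2 (0.252 to 0.417%) overlapped both knockout intervals. That of wild-type replicate 1 overlapped neither. The shortest list, knockout replicate 1, had the highest share and the longest, wild-type replicate 1, the lowest. These shares therefore cannot tell a difference between genotypes from list length.

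The differential regions of chromosomes 9, 10, 13, 15 and 19 (wild type) and 1, 17 and 18 (knockout) may reflect whole chromosomes that differ between the clone and the wild-type cells, for example in copy number. Across 20 chromosomes, the knockout to wild-type ratio of peak shares outside the lists followed the balance of the lists (Spearman rho 0.733, permutation p = 0.00037, and Pearson r 0.818, permutation p = 2e-05; without the 2 farthest chromosomes rho 0.635 and r 0.731). These permutations shuffle chromosomes, which are not independent, and the lists and the shares may come from the same libraries. The p-values therefore carry no error between libraries. Chromosomes 8 and 12 had log2 ratios of 0.17 and 0.18 and held 4 and 3 knockout-enriched regions against 11.2 and 7.63 expected (Fisher's exact adjusted p = 0.0415 and 0.172), and 2 and 1 wild-type-enriched regions against 11.3 and 7.69 (adjusted p = 0.00758 and 0.0269). List length is argued against, since the ratio of the short to the long list of the same genotype gave a mean rho of -0.0233. A change confined to the listed regions is argued against as well. In all 4 pairs, the knockout minus wild-type rank difference outside them was at least 8.63 percentile points higher on knockout-led than on wild-type-led chromosomes. Between replicates the gaps were -0.00690 and 0.0605. The chromosomes were chosen from lists that may rest on these libraries, and the 4 pairs share libraries, so their equal signs are not independent. On the leading chromosomes 59.0% (chromosome 1) to 70.3% (chromosome 13) of these regions moved with the list. Over all chromosomes 47.6% ranked higher in knockout. Sites below the authors' threshold may lie outside the lists, so many separate changes stay open. Peak lists do not measure copy number, so a chromatin change spread over whole chromosomes stays open, and with 1 knockout clone an effect of losing Ranbp2 and a difference that arose in cloning are confounded.

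Chromosome 10, which carries Ranbp2, had the most wild-type-enriched regions, and a loss of the part beyond the edited site could give that. Beyond Ranbp2 lay 34 of its 41 regions, against 826 of 1147 background regions (odds ratio 1.89, 0.828 to 4.30, Fisher's exact p = 0.155), which does not decide it. Peaks before Ranbp2 also made up less of the knockout lists (1.17% and 1.20%) than of the wild-type lists (1.74% and 1.43%), as did peaks beyond it (3.67% and 3.49% against 3.97% and 3.96%). The mean rank shift was -2.38 points (SE 1.73 over regions) before and -5.15 (SE 0.814) beyond Ranbp2, so loss of that part and a shift of the whole chromosome cannot be told apart with these few regions.

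The excess of gene ends in the wild-type list lay on its leading chromosomes (odds ratio 2.79, 1.95 to 3.98, against background of the same chromosomes, and 0.435 elsewhere). A difference in gene density between chromosomes is therefore argued against there, while gene density within a chromosome was not tested. The 1.58 within chromosome strata joins opposite values. Peak strength may account for part of the excess and stays open, since the regions on the leading chromosomes ranked at a median percentile of 83.7 against 51.0. Their odds ratio within 5, 10 and 20 strength bins was 1.48 (1.02 to 2.15), 1.47 (lower bound 1.01) and 1.39 (0.952 to 2.02), or 0.862 in 5 bins over all chromosomes. Strength does not explain the lack of gene ends in wild-type-enriched regions elsewhere (0.272, 0.142 to 0.521, in 5 bins) or in the knockout list (0.153 within bins), nor does chromosome in the knockout list (0.205 within strata). A genome-wide tilt away from gene ends in knockout cells stays open, since outside the lists the knockout minus wild-type rank difference was lower at gene ends than at other regions in all 4 pairs (-1.17 to -6.72 points, mean -3.94), but the knockout replicates differed from each other by -3.84. An effect of losing Ranbp2 on distal regions was not tested apart from a difference of the clone.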
